A study of Mus musculus with 126 samples.

How the data were processed

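The series holds 126 single cells from the brain of C57BL/6J mouse embryos at embryonic day 16.5. Cells had been sorted as CD45+ F4/80+ CD11b+ Ly6C-, a gate for tissue macrophages that leaves out Ly6C-bearing monocytes, and captured on a Fluidigm C1 microfluidic circuit. Per the labels' protocols, cDNA was made with the SMARTer Ultra Low kit, libraries with Nextera XT, and single reads of 51 cycles were taken on a HiSeq2000. The protocol kept cells whose cDNA was of high quality and above a minimum concentration, so cells of very low RNA content had been left out before sequencing. SMARTer cDNA carries no molecular identifiers and the kit does not mark strand.

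The deposited values were TPM (RSEM transcript abundance scaled to a fixed sum per cell), made by the authors for each gene symbol and cell. RSEM 1.2.19 and the GRCm38 build are named per the submitters' processing notes. The aligner, the annotation release and any filters are not given in the sources used here. TPM keeps no depth, so the depth of each cell is unknown, and precision is described by the spread over cells. Of 43280 rows, 4 carried a spreadsheet date in place of a symbol and were left out, which left 43276 genes. The TPM of these genes summed to between 992333 and 999999.9 per cell. For 43 symbols the values had more than the usual decimals, as a mean over several gene identifiers would. Reads of 51 bases can be shared between near-identical genes, so values of multigene families (Ms4a, Ifitm, Ccl, Ifit, Ly6) are uncertain at the level of the single gene. Antisense and overlapping genes cannot be told apart from their partners without strand. Gene positions were taken from GENCODE M21 on GRCm38, in which 39443 of the symbols occurred (91.1%). The table uses the older symbols Emr1 for Adgre1 (F4/80) and Gpr56 for Adgrg1, matched through RefSeq synonyms. Of 359 genes in the fixed lists, 358 were measured.

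All cells carry the same labels, and no animal, litter or chip is named. The cells are therefore 1 sample, cells are not replicates, and no test, p-value or count of significant genes was made. Values are given as a mean and SD over cells of log2(TPM + 1), as differences of such means, and as shares of cells with exact Clopper-Pearson 95% intervals, which cover counting error only. Differences on this scale understate the change of genes with low values. A gene was counted as detected at 1 TPM or more. Thresholds of 5 and 10 TPM were alternatives, and one of 100 TPM was added after seeing the data, except for markers of other cell types, for which it had been set beforehand.

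The design text says that the 2 macrophage populations became apparent only after processing. No annotation of cells to them was used here, so classes were rebuilt and may differ from those of the study. Cells with at least 1000 genes at 1 TPM or more were kept (125 of 126). The 2000 most variable genes (variance of log2(TPM + 1) above a running median over 101 genes ordered by mean, genes detected in at least 5 cells) entered a principal component analysis. Every gene of the fixed lists and every mitochondrial gene was kept out of it. Ward clustering of the first 10 components gave 4 clusters. A cluster was called microglia-like or non-parenchymal macrophage-like where the median difference of that marker list against the other cells was above 0, that of the other list was below 0, and at least 3 of its markers stood at 10 TPM or more in at least 50% of its cells. The numerical form of this naming rule was set after the files were seen. The marker lists come from general knowledge of the field, which can include work on cells of this kind.

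The 10 leading genes of each cluster, by fold of mean TPM + 1, were compared with the markers. When genes had to be detected at 1 TPM or more in 50% of a cluster's cells, the monocyte marker Ccr2 entered the leading genes of microglia-like cluster 2, and no microglia marker did. Ccr2 stood at 10 TPM or more in 1 of the 30 cells of that cluster and in 2 of the other cells. The requirement was then raised to 10 TPM, a choice made after seeing this, under which no marker of another cell type led clusters 1, 2 or 3. The leading genes of clusters 2 and 3 then still held no microglia marker, so these clusters owe their name to the marker lists alone. For this reason the medians of the marker lists, and of some lists whose median changed sign, are also given with microglia-like cluster 2 alone and with cluster 3 alone. Cluster 4 fulfilled neither naming rule and stayed unnamed.

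For genes outside the lists, genes were split at random into 2 parts. Cells were clustered on 1 part and the genes of the other part were described by those clusters, then the parts were exchanged, so that no gene is described by clusters it helped to make. The rule for named genes allows every member of the fixed lists, and takes the 12 genes with the largest difference in each direction among genes in no list that were detected in at least 50% of the cells of the higher class. Predicted genes (Gm numbers, Rik clones) and mitochondrial genes were passed over. Results for some list genes are not reported here. The samples, lists, named-gene rule, tests and alternatives (numbers of clusters and variable genes, Leiden clustering, pseudocounts of 0.1 and 10, cell and gene filters, 2 other scalings, detection thresholds) were fixed before the data were examined, except where stated otherwise.

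No doublet caller was run, since a table of 125 cells without counts gives it little to work on. Cells with both Xist and a Y-linked gene were counted as candidate doublets, and leaving them out was an alternative. The method was tested on simulated data. Each gene's values were redrawn over 125 cells, all 43276 genes entered, and 200 genes were changed 8-fold between the simulated classes. The markers of each class were raised 8-fold plus a fixed amount above the 10 TPM of the naming rule, which made naming easy. All 125 cells were named, and 115 (92.0%) received the right class. Genes were redrawn independently, in classes of like size and with no cluster of few genes. This share therefore does not measure the accuracy of the classes in the real cells. The direction was recovered for 193 of the 200 changed genes (96.5%), with a median absolute error of 0.69 on the log2 scale. Unchanged genes had a median absolute difference of 0.30. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, leidenalg 0.10.2 and matplotlib 3.10.9 were used.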

Results

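Single-cell transcriptomes were obtained from macrophages of the mouse brain at E16.5. All cells came from the same sort (CD45+ F4/80+ CD11b+ Ly6C-) and form 1 group. They addressed whether the embryonic brain holds separate populations of microglia, the macrophages of the brain tissue itself, and of non-parenchymal macrophages, which line the meninges, vessels and choroid plexus. Between 380 and 7067 genes per cell stood at 1 TPM or more (median 4857). The cell with 380 genes was left out and all others were analysed. With 1 group and no named animals there are no replicates, and every error given is the SD over cells or a counting interval.

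The sorted cells carried the transcripts of macrophages. Csf1r, the receptor for CSF1 and IL-34, was detected in 99.2% of these cells (95% interval 95.6 to 99.98) with a median of 601 TPM. C1qb, a chain of complement C1q, was detected in every cell (median 3549 TPM), and Tyrobp, a signalling adaptor of myeloid receptors, in 99.2% (median 3989 TPM). The genes of the sort antigens were detected in most cells: Ptprc (CD45) in 93.6% (87.8 to 97.2), Emr1 (F4/80) in 95.2% (89.8 to 98.2) and Itgam (CD11b) in 84% (76.4 to 89.9). Ly6c1 was detected in 2 cells and Ly6c2 in 6, and neither reached 100 TPM in any cell. The transcription factor gene Spi1 was detected in 48.8% of cells (39.8 to 57.9), with a median of 0.60 TPM. At 10 TPM or more, Ptprc was counted in 77.6%, Emr1 in 79.2% and Itgam in 52.8% of cells.

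Clustering that left out all marker genes separated 2 macrophage classes. The microglia-like class held 58 cells (46.4% of all, 95% interval 37.4 to 55.5) in clusters 2 (30 cells) and 3 (28 cells). The non-parenchymal macrophage-like class held 50 cells (40%, 31.3 to 49.1) in cluster 1. The other 17 cells (13.6%, 8.13 to 20.9) formed cluster 4 and stayed unnamed. The microglia marker mean exceeded the non-parenchymal macrophage marker mean in 56 of the 58 microglia-like cells, and the reverse held in 45 of the 50 non-parenchymal macrophage-like cells. The exceptions, 2 and 5 cells, kept the class of their cluster and enter every class mean, SD and share. The 2 microglia-like exceptions held Pf4 at 16533 and 13389 TPM, so their markers were those of the other class. Of the 5 non-parenchymal macrophage-like exceptions, 1 held Sall1 at 812 TPM, and the others held it at 0.19 TPM or less. These others held Mrc1 at 118.8 to 828.28 TPM and Ms4a7 at 76.35 to 3416.13 TPM. In them Pf4 reached at most 7.56 TPM and Lyve1 at most 2.38 TPM. Their marker means were 4.29 to 5.38 for microglia and 2.92 to 3.95 for non-parenchymal macrophages, so their markers were mixed. The median number of genes was 4884 in microglia-like, 5276 in non-parenchymal macrophage-like and 2109 in unnamed cells. The median mitochondrial share was 5.29%, 6.92% and 33.5% of TPM in the same order. When cells were clustered on either random part of the genes, 82 of the 90 cells named in both received the same class (91.1%, 83.2 to 96.1). The parts left 20 and 35 cells unnamed and called 48 and 36 cells non-parenchymal macrophage-like. The non-parenchymal macrophage-like share fell to 29.6% with 4000 variable genes, and with 2 clusters no cluster could be named.

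**Figure D1:**
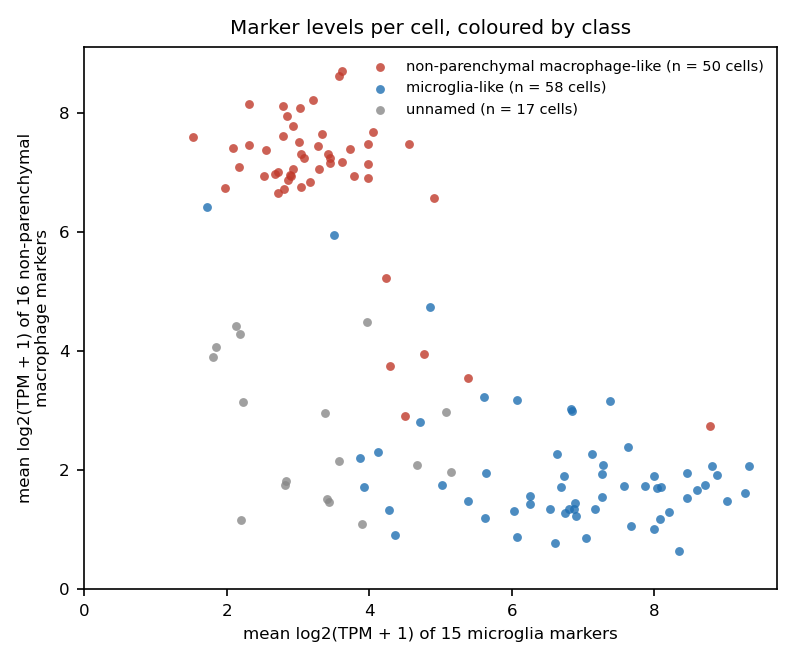
Mean log2(TPM + 1) of the 15 microglia markers (x axis) and of the 16 non-parenchymal macrophage markers (y axis) for each cell, coloured by class. Microglia-like cells averaged 6.76 and 1.94 on the x and y axes, non-parenchymal macrophage-like cells 3.38 and 6.91, and the 17 unnamed cells 3.21 and 2.66.

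The classes differed in nearly all markers of their types. The markers had not entered the clustering, but their medians named the clusters, so the direction of each list median was set by the naming. Of 16 non-parenchymal macrophage markers, 15 were higher by at least 1 on the log2(TPM + 1) scale in the class of that name and none in the other (median difference 5.02). Pf4, a chemokine, had a mean of 12.12 ± 3.47 (SD, n = 50 cells) against 2.63 ± 2.83 (n = 58 cells) in microglia-like cells, a difference of 9.49. F13a1, the A subunit of coagulation factor XIII, differed by 8.27, the hyaluronan receptor gene Lyve1 by 7.78, Ms4a7 by 7.34 and Mrc1, the mannose receptor CD206, by 7.21. Of 15 microglia markers, 14 were higher by at least 1 in microglia-like cells and none in the other class (median difference -2.50). Sparc, a secreted matrix protein gene, had a mean of 9.86 ± 2.98 (n = 58) against 2.75 ± 1.86 (n = 50), a difference of -7.12. Olfml3 differed by -6.37, Siglech by -4.71, the transcription factor gene Sall1 by -4.46 and Tmem119 by -3.98. Sall1 reached 10 TPM in 38 of 58 microglia-like cells (65.5%, 51.9 to 77.5) and in 1 of 50 non-parenchymal macrophage-like cells (2%, 0.0506 to 10.6). That 1 cell, with Sall1 at 812 TPM, had a marker mean of 8.78 for microglia and 2.75 for non-parenchymal macrophages, so its markers were those of microglia.

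The separation was graded for several markers. Fcrls (-0.29) and Siglec1 (0.44) differed by less than 1. P2ry12, the ADP receptor used to mark microglia, differed by -3.54, yet reached 10 TPM in 40 of 50 non-parenchymal macrophage-like cells (median 66.6 TPM, against 2050 TPM in microglia-like cells). Cx3cr1, the fractalkine receptor gene, stood at medians of 327 and 1391 TPM in the respective classes. Stab1, a scavenger receptor gene, had a median of 132 TPM in microglia-like and 2149 TPM in non-parenchymal macrophage-like cells. The difference exceeded the larger SD of the classes for 11 of the 16 and for 7 of the 15 markers. Mrc1 lies on chromosome 2 from 14229392 to 14332057, Pf4 on chromosome 5 from 90772435 to 90773383 and Sall1 on chromosome 8 from 89027235 to 89044162 (GRCm38), and all are annotated as protein-coding. Against non-parenchymal macrophage-like cells, microglia-like cluster 2 alone gave list medians of 5.04 and -2.40 and cluster 3 alone 5.01 and -2.91, for the non-parenchymal macrophage and microglia markers.

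**Figure D2:**
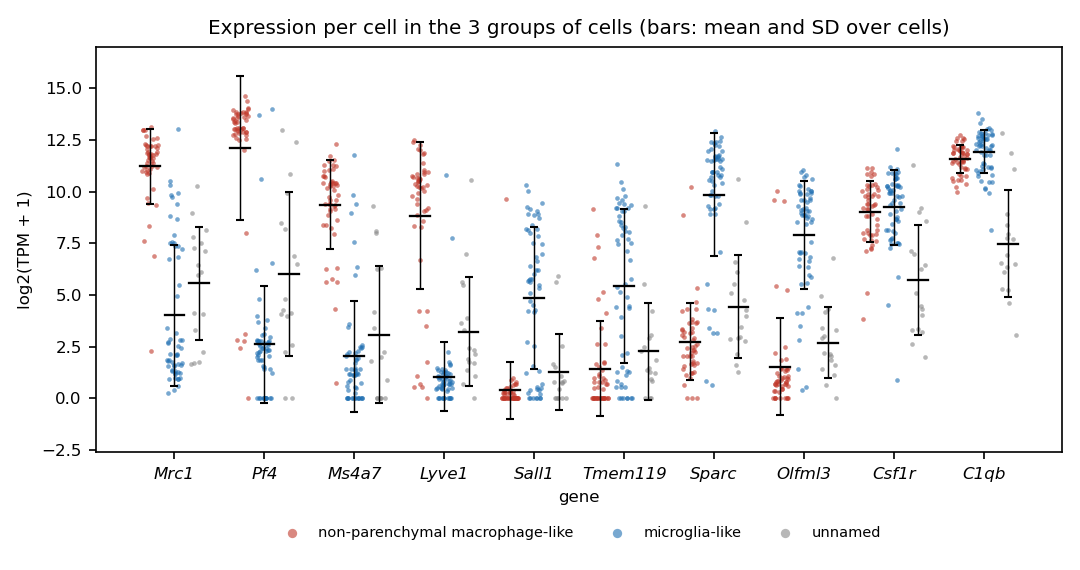
Log2(TPM + 1) of 10 genes in each cell, with the mean and SD over the 50 non-parenchymal macrophage-like, 58 microglia-like and 17 unnamed cells. The left 4 genes are non-parenchymal macrophage markers, the next 4 are microglia markers, and Csf1r and C1qb are shared macrophage genes, which differed by -0.22 and -0.34 between the named classes.

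Scavenger and endocytic receptor genes divided between the classes once the naming markers among them were set aside. Of 17 measured members, 10 were higher by at least 1 in that class and 3 in microglia-like cells (median difference 2.94). The list shares Mrc1, Lyve1, Stab1, Cd163, Cd36 and Colec12 with the markers, and of the 11 other members 4 were higher in that class, 3 in microglia-like cells and 4 within 1 (median difference 0.00, a tally chosen after seeing the data). Among members outside the markers, the scavenger receptor gene Msr1 differed by 4.98, Fcgrt (the neonatal Fc receptor) by 4.83, Nrp1 (neuropilin) by 3.59 and Gas6, which encodes a ligand of TAM receptors, by 3.33. Higher in microglia-like cells were Lrp1 (-2.14), the TAM receptor gene Axl (-1.99) and Scarb2 (-1.04). In the phagocytosis and lipid handling list of 16 genes, 4 were higher in non-parenchymal macrophage-like and 3 in microglia-like cells. Igf1, a growth factor gene, differed by 5.03 and reached 10 TPM in 39 of 50 against 12 of 58 cells, whereas the tetraspanin gene Cd9 differed by -3.92. Apoe was abundant in both classes, with a difference of 1.26.

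Signalling and transcription factor genes divided between the classes. In the TGF-beta and CSF1 signalling list of 14 genes, 3 were higher in microglia-like cells: Skil, a repressor of SMAD signalling (-4.21), the receptor gene Tgfbr1 (-3.27) and Csf1 (-1.49). Nrros, which encodes a partner of latent TGF-beta, was the member higher in the other class (2.78). Of 23 transcription factors, 4 were higher in microglia-like cells (for example Irf8 at -1.54, and the microglia markers Sall1 and Sall3) and 8 in non-parenchymal macrophage-like cells, among them Etv1 (2.40), Klf4 (1.82), Klf6 (1.46) and Maf (1.44). Of 8 genes in the purinergic receptor list, 5 were higher in microglia-like cells and 1, P2rx4 (1.18), in the other class. However, P2ry12, P2ry13 and Gpr34 are microglia markers. Of the 5 others, 2 were higher in microglia-like cells, Adora3 and Entpd1, and Entpd1 encodes an enzyme and not a receptor. Of 10 integrin genes, 4 were higher in microglia-like cells, with Itgam at -3.25, and 2 in the other class, Itga9 (1.41) and Itga4 (1.15). The difference exceeded the larger SD for 2 of the transcription factors and for 2 of the TGF-beta and CSF1 genes.

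Chemokine genes went both ways within the list of 17. Higher in non-parenchymal macrophage-like cells were Ccl7 (3.30), Ccl2 (2.89), Ccl24 (2.87) and Cxcl2 (1.72). Higher in microglia-like cells were Ccl4 (-4.53), the interleukin gene Il1a (-3.72), Cxcl16 (-1.67), Ccl3 (-1.54) and Ccl6 (-1.33). None of these differences exceeded the larger SD, since each gene was high in some cells of a class and absent from others. Ccl2, for example, had a mean of 8.16 ± 4.95 in the 50 and 5.27 ± 4.89 in the 58 cells. Of 15 immediate early and heat shock genes, 3 were higher in non-parenchymal macrophage-like cells (Dusp1 by 1.88) and 2 in microglia-like cells (Atf3 by -1.67), with a list median of 0.16.

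Macrophage core genes went both ways, and complement C1q genes were alike in the classes. C1qa, C1qb and C1qc all differed by less than 1. Of 14 macrophage core genes, 4 were higher in each class and the median difference was 0.17. Lysozyme (Lyz2) differed by 3.08, Cd68 by 1.35, Cd81 by -3.38, Trem2 by -2.77 and the cathepsin gene Ctss by -2.02. Among MHC class II genes, 4 of 5 reached 10 TPM in no cell, and Cd74 reached it in 7 of 50 non-parenchymal macrophage-like and 0 of 58 microglia-like cells, which allows a share of up to 6.16% by the exact interval. In the interferon response list, Bst2 (2.17) and Ifi27l2a (1.53) were higher in non-parenchymal macrophage-like cells and the other 10 members differed by less than 1. The list median was 0.42 against microglia-like cluster 2 alone and -1.18 against cluster 3 alone, in which 7 of the 28 cells averaged 6.22 over the list and the other 21 averaged 0.86. Of 7 housekeeping genes, Hprt (2.80) and Gapdh (1.01) were higher in non-parenchymal macrophage-like cells and 5 differed by less than 1. Cd14 (1.12) and Gapdh turned to -0.13 and -0.20 when cluster 3 alone stood for the microglia-like cells.

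**Figure D3:**
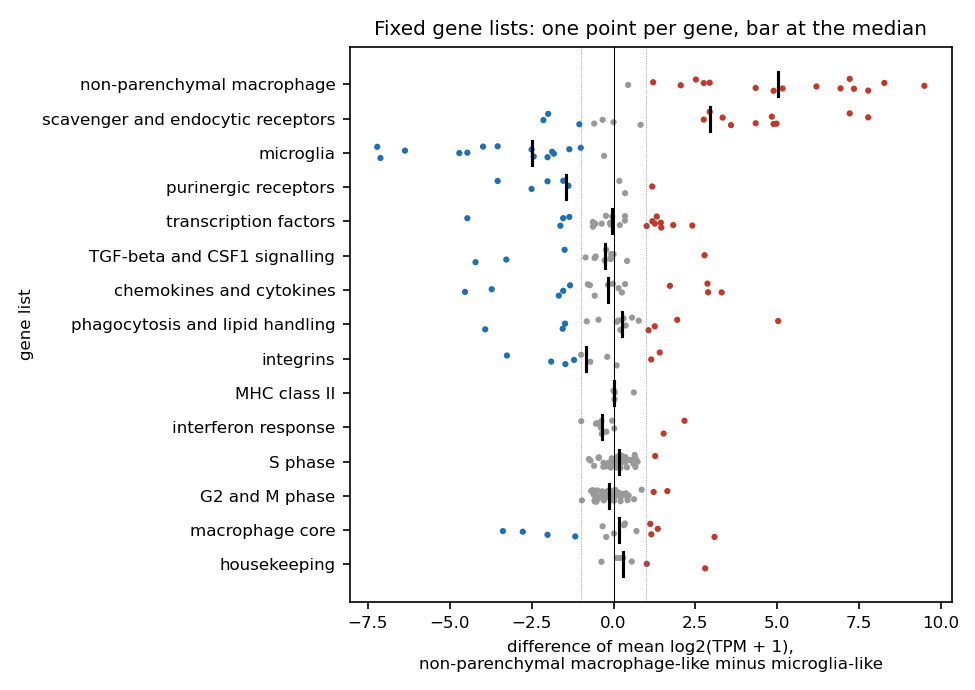
Difference of mean log2(TPM + 1), non-parenchymal macrophage-like (50 cells) minus microglia-like (58 cells), for each gene of 15 fixed lists. Points at 1 or above are red and points at -1 or below are blue, grey points lie between the dotted lines, and black bars mark list medians, from 5.02 for the non-parenchymal macrophage markers to -2.50 for the microglia markers.

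Outside the lists, the 12 genes with the largest difference in each direction were taken, with each gene described by clusters made without its part of the genes. Ms4a4a, which encodes a membrane protein of the same family as Ms4a7, was higher in non-parenchymal macrophage-like cells by 6.74 (9.78 ± 2.02, n = 36 cells, against 3.04 ± 4.10, n = 54 cells). Lgals1 (galectin-1) followed with 6.72, Ifitm2 with 6.36, Blvrb (biliverdin reductase B) with 6.27 and Pmp22 with 6.14. Fcna (ficolin A, a lectin of the complement system), Dse (dermatan sulfate epimerase), Serpinb6a, Tmem106a, Ms4a6c, S100a1 and Eps8 differed by 5.23 to 4.57. In microglia-like cells, Mpeg1 (perforin-2) was higher with a difference of -5.88 (6.74 ± 2.54, n = 54, against 0.87 ± 1.79, n = 36). F11r, a junctional adhesion molecule gene, stood at -5.81 and reached 10 TPM in 40 of 54 microglia-like and 0 of 36 other cells. Ly6e (-5.77), the inhibitory collagen receptor gene Lair1 (-5.55), the immunoglobulin mu chain gene Ighm (-5.40) and Plxdc2 (-5.27) followed. Cd52, Ldhb, Lpcat2, Asph, Golm1 and Rogdi differed by -4.89 to -4.27. For all 24 genes the difference exceeded the larger SD of the classes. The order mixes 2 sets of classes: genes of 1 part were described by 36 against 54 cells, as Ms4a4a was, and those of the other by 48 against 57, as Blvrb was. In the main classes, which a gene may have helped to make, some differences were larger (Ms4a4a 7.95, Lgals1 7.34) and others smaller (Mpeg1 -4.78, Ighm -3.94). The genes were picked for their size among 4371 genes, so the differences of the leading genes may be overstated.

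Without any clustering, Sall1 and Tmem119 were found at 10 TPM or more in the same cell as Mrc1, Pf4 or Ms4a7 less often than independence would give. At 10 TPM or more, Mrc1 and Sall1 were both present in 12 cells, where independence would give 26.6, and Mrc1 alone in 69 and Sall1 alone in 29. Pf4 and Sall1 were both present in 5 cells (22 under independence), Ms4a7 and Sall1 in 2 (20.7) and Tmem119 was present with Mrc1 in 18 (31.1), with Pf4 in 7 (25.7) and with Ms4a7 in 9 (24.2). At 1 TPM or more, Mrc1 and Sall1 were both present in 44 cells (35.2%, 47.2 cells under independence), because Mrc1 was then detected in 94.4% of cells. Of the 58 microglia-like cells, 51 held Mrc1 at 1 TPM or more and 20 at 10 TPM or more, with a median of 3.94 TPM. P2ry12 was detected in every cell at 1 TPM. At 10 TPM it was found with Mrc1 in 66 cells (68.7 under independence), with Pf4 in 54 (56.8) and with Ms4a7 in 49 (53.4), a level that most cells reach for P2ry12. At 100 TPM these pairs stood at 38 (46.2), 23 (34.3) and 24 cells (31.8). Detection of Mrc1 or P2ry12 at 1 TPM thus does not part the classes.

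Cell cycle genes were found in both classes. Mki67, a marker of cycling cells, was detected in 14 of 58 microglia-like cells (24.1%, 13.9 to 37.2) and in 11 of 50 non-parenchymal macrophage-like cells (22%, 11.5 to 36), and the intervals overlap. At 100 TPM the shares were 15.5% (7.35 to 27.4) and 8% (2.22 to 19.2). At 10 TPM or more it was counted in 12 and 7 cells, Top2a in 21 and 13, and Cdk1 in 15 and 21. Of 42 S phase genes, 1 differed by at least 1 between the classes, Cdc6 (1.27), and of 52 G2 and M phase genes 2 did, Lbr (1.64) and Cdk1 (1.23). At least 10 of the G2 and M phase genes stood at 10 TPM or more in 16 microglia-like, 14 non-parenchymal macrophage-like and 2 unnamed cells. Top2a was detected at 1 TPM in 89.7% and 72% of microglia-like and non-parenchymal macrophage-like cells.

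Markers of other cell types were rare apart from Pax6, of the neural progenitor list, and Cd79b, of the lymphocyte list. In 29 cells (23.2%, 16.1 to 31.6) at least 2 markers of 1 list of another cell type stood at 10 TPM or more, and 27 of them did so for neural progenitor markers. Pax6, a transcription factor gene of neural progenitors, reached 10 TPM in 94.4% of cells, with many in every class, and Nes (-1.19) and Slc1a3 (-1.02) were higher in microglia-like cells. In most cells the count of 27 thus needed only 1 marker besides Pax6. Sox2 and Hes5, of the same list, stood at 0 TPM in every cell, while Slc1a3, Nes and Fabp7 reached 10 TPM in 12, 10 and 7 cells. The list was thus expressed in part only. No cell held 2 monocyte, neutrophil, mast cell and basophil, lymphocyte, dendritic cell, oligodendrocyte lineage or mural cell and fibroblast markers at 10 TPM, and 1 cell each held 2 erythroid, neuron or endothelial markers. The B cell receptor gene Cd79b reached 10 TPM in 50 cells, 24 of them non-parenchymal macrophage-like and 23 microglia-like. At 100 TPM, 2 markers of 1 list were found in 0.80% of cells, and 3 markers at 10 TPM in none.

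The cells came from embryos of both sexes. At 10 TPM or more, 39 cells held Xist, the transcript of the inactive X chromosome, without a Y-linked gene, 54 held a Y-linked gene (Ddx3y, Eif2s3y, Kdm5d or Uty) without Xist, 8 held both and 24 neither. At 1 TPM, 54 cells (43.2%) held both, and at 100 TPM 1 cell did. In the 28 cells with Xist at 100 TPM or more, Uty and Kdm5d had medians of 3.435 and 1.41 TPM, and Ddx3y and Eif2s3y of 0 TPM. Low levels of Uty and Kdm5d can thus meet the call at 1 TPM, which is not a count of doublets. Both classes contained cells of either kind at 10 TPM, with 18 Xist and 29 Y cells among microglia-like and 19 and 23 among non-parenchymal macrophage-like cells. X inactivation genes (list median 0.25) and Y-linked genes (-0.52) differed by less than 1 between the classes.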

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

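The threshold of 100 TPM (except for other cell types), the lists without cells of few genes or high mitochondrial share, and clusters 2 and 3 taken alone were chosen after seeing the data. Over 14 other settings, 0 to 13 of the cells named in both changed class, and 2 clusters gave no named class and so no value. With 4000 variable genes the non-parenchymal macrophage-like share was 29.6% (main 40%), and the median difference of all genes was 0.20 (main 0.02). The pseudocount sets the size of log differences: the non-parenchymal macrophage marker median was 6.93 at 0.1 and 3.52 at 10, and the scavenger receptor median 3.82 and 1.90. Over all settings the marker medians ranged from 3.52 to 6.93 and from -3.15 to -2.07. Of 97 list genes that differed by at least 1, all kept their sign under 17 settings except Cd14 (-0.13) and Gapdh (-0.20) with cluster 3 alone, where the cause was not tested. With clusters 2 and 3 alone, several list medians near 0 changed sign, for example 0.68 and -0.18 for macrophage core (main 0.17), 0.52 and -0.19 for housekeeping (main 0.29), 0.32 and -0.13 for S phase (main 0.16) and 0.42 and -1.18 for interferon response (main -0.37). The 24 named genes outside the lists kept their sign in all 144 values, and 8 to 12 of each 12 were named again. In 1 of these settings, with no requirement on the share of cells, the 24 values equal the main ones by construction.

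Shares follow the detection threshold by construction. At above 0, 5, 10 and 100 TPM, Mrc1 with Sall1 was found in 67.2, 12.8, 9.60 and 2.40% of cells (main 35.2%) and Xist with a Y-linked gene in 76, 15.2, 6.40 and 0.80% (main 43.2%). At 5, 10 and 100 TPM, Ptprc was found in 80.8, 77.6 and 62.4% and Emr1 in 86.4, 79.2 and 60%. Itgam was found in 94.4, 58.4, 52.8 and 34.4% at above 0, 5, 10 and 100 TPM. Mki67 above 0 was found in 50% of microglia-like and 52% of non-parenchymal macrophage-like cells, and at 100 TPM in 8% of the latter. Cells with 2 markers of another type came to 74.4% at 1 TPM and 0.80% at 100 TPM, and to 0% with 3 markers (main 23.2%). No paired analysis was possible because the cells form 1 group and no result comes from a test. The depth of each cell is unknown.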

Other observations

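The tests of a neural type, of shared background, of library complexity, of cells of 1 sex and of carry-over for single markers were chosen after the results were seen, and cells at 6 clusters were described after seeing the data.

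With 6 clusters, the 50 non-parenchymal macrophage-like cells divided into 31 and 19 cells that differed in cell cycle genes. The S phase list, which had not entered the clustering, averaged 3.37 ± 1.79 (SD, n = 19 cells) against 1.04 ± 0.31 (n = 31 cells), and the G2 and M phase list 2.19 ± 1.56 against 1.2 ± 0.90, a difference below the larger SD. The 19 cells also had more genes (median 5622 against 5190), and library complexity was not separated from the cycle. The non-parenchymal macrophage markers averaged 7.07 and 6.81 and the scavenger and endocytic receptors 5.01 and 4.75. Other cycle genes were free to enter the clustering, so the division itself is not independent of the cycle.

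Low levels of non-parenchymal macrophage markers were present in most microglia-like cells, with Pf4 at a median of 4.08 TPM and Mrc1 at 3.94 TPM. For pairs of cells captured together, the bound was 0.25 times the summed-marker median of the other class, which 5.17% of microglia-like cells exceeded. The summed markers had a median of 484 TPM, against 27363 TPM in the other class, so most cells lay below the level set for pairs. The class was named for low values of these markers, so few cells could pass the bound, and pairs are not excluded by it. Carry-over of RNA between cells may explain part of the low levels. The share of Y-linked RNA in Xist cells over the share of the markers in microglia-like cells was 0.603. That lies inside the range of 0.25 to 4 set for carry-over beforehand. This test was set aside after it was seen because Eif2s3y made up 56.4% of the Y-linked sum. That reason bears little on the share tested, which is a median. In the Xist cells Eif2s3y had a median of 0 TPM, against 3.435 TPM for Uty and 1.41 TPM for Kdm5d. As a share of the mean over all cells, these medians were 0% for Eif2s3y and Ddx3y, 4.89% for Uty and 5.69% for Kdm5d. Carry-over alone would give like shares. The ratio, though inside the range set beforehand, thus decides nothing for the summed markers. Among abundant markers, Stab1 kept 95.8 times the share of Pf4, which carry-over alone would not give, and although the median shares of Mrc1, Pf4, Dab2 and F13a1 lay within 4.72 times of each other, the upper quartiles of Mrc1 (161 TPM) and Dab2 (244 TPM) kept 75.6 and 160 times the share of that of Pf4 (5.89 TPM). Carry-over as the whole cause is thus argued against for Stab1, and for Mrc1 and Dab2 in the cells where they are highest, while it fits the median levels of Mrc1, Pf4, Dab2 and F13a1 without being shown, transcription in the cells themselves was not tested, and no biological explanation was tested since the labels give 1 group.

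The 17 unnamed cells had few genes (median 2109), a high mitochondrial share and lower macrophage genes, with C1qb at a median of 121.5 TPM, and were led by Smco1, Cp and Calb1 (median 5104 TPM, against 605 TPM in the other cells), with Pax6 and Bhlhe41 further down (genes outside the lists were chosen after their values were seen). A neural type for most of these cells is argued against, since 0 of 18 neuron, neural progenitor and oligodendrocyte markers other than Pax6 had a median of 1 TPM or more, but a few neural cells are not excluded (Stmn2 reached 10 TPM in 2 of the 17 and Fabp7 in 1), and Calb1 and S100b (10 TPM or more in 5 of 17 cells), which neural cells can express, are not among those 18. Damaged macrophages with less RNA over a background shared by all cells could explain them, in which case the leading genes would rise in other cells as fewer genes are detected. The median Spearman rho of these 10 genes with the number of genes, across cells that are not replicates, was -0.109 in microglia-like and 0.0917 in non-parenchymal macrophage-like cells. The value in non-parenchymal macrophage-like cells reached the bound set against this explanation. Its quartiles over the 10 genes (-0.0839 to 0.212) span 0, as do those in microglia-like cells (-0.291 to 0.0864). After seeing this the test was taken as open, but these quartiles are a spread over genes and not an error of the median. The test thus does not favour a shared background, and no biological explanation was tested.

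At 6 clusters, 7 cells of the microglia-like class formed a cluster that fulfilled neither naming rule (microglia markers 5.20 ± 1.06, against 6.70 and 7.36 in the microglia-like clusters) and had high interferon response genes (list mean 6.22 ± 1.55, SD, against 0.33 to 1.51 in the other clusters). The ranges over cells overlapped, since the list means of these 7 cells ran from 3.71 to 8.27. The highest other cells reached 3.99 in the microglia-like cluster of 21 cells and 4.42 in the non-parenchymal macrophage-like cluster of 31 cells. The interferon list had not entered the clustering, but other interferon-induced genes were free to. Against the other 51 microglia-like cells, Irf7 was higher by 7.76, Ifit3 by 7.59, Oasl2 by 6.96 and Usp18 by 6.89, and Irf7 reached 10 TPM in 7 of 7 against 3 of 51 cells. A difference in library complexity is argued against by the median of 4860 genes in these cells, inside the quartiles of the others (4367 to 5544), and reads shared between gene copies are argued against by 5 of 5 genes outside the multigene families (Irf7 and Usp18, for example) being higher by at least 1. At 10 TPM, 5 of the 7 cells held Xist without a Y-linked gene, 1 a Y-linked gene and 1 neither, which is 5 of the 18 microglia-like cells with Xist alone and 1 of the 29 with a Y-linked gene alone, and sex or descent from few embryos may matter: none (0%) of the 13 other cells with Xist alone reached the interferon list range of the 7, but they are what was left after the 7 were taken out, so this decides nothing, and no biological explanation was tested.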
